A study of Mus musculus and Homo sapiens and Macaca mulatta with 62 samples.

How the data were processed

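The series held 62 samples, and 36 of them gave the values used, either through a file of their own or through a list made from pooled samples. The H3K27me3 samples and the IgG controls, 26 samples in all, were not analysed here. Per the labels, GO-CaRT reads, those of the histone marks included, were aligned by the authors with Bowtie2, duplicates were handled with Picard, and the builds named are mm10, hg38 and rheMac8; the versions of Bowtie2 and Picard are not given in the sources used here. The domains were called by the authors. Per the file headers and labels, the caller was EPIC2 for HEK293T, macaque cortex and cortex NPC H3K9me2, and EDD for lung replicate 1 and cultured NSCs. For the other lists the caller is not given in the sources used here. Their layout matched the EPIC2 lists in NPCs and the EDD lists in liver, lung replicate 2 and NIH/3T3, so tissues and callers partly coincide. Per the labels, the NPC LaminB lists joined PFC with V1 and MGE with LGE samples, the cortex NPC H3K9me2 list came from PFC alone, and macaque cortex joined PFC with V1.

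The deposited lists of NPCs and HEK293T give a p-value and a score per domain, whose columns were identified from the header of the H3K9me2 list. The liver, lung, NIH/3T3 and cultured NSC lists give a score per domain from the authors' caller, whose scale is not comparable between lists. The macaque lists give positions alone. Per the file headers, the cortex NPC H3K9me2 list adds counts of reads per domain in the H3K9me2 and control libraries, a false discovery rate and a log2 fold over control, which were not used here. Scores were used only to choose stricter domains and to trim lists to equal length. No list gives a library total, so no depth, interval or floor was computed for domains.

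Per the file headers, RNA files hold estimated counts per transcript from kallisto (0.43.1, run by the authors against GRCm38 transcripts), not scaled by depth; sleuth 0.30.0 is named for their own test. Each file lists 133849 transcripts with Ensembl identifiers, and the files used here do not pair these with genes. The tests were therefore run on transcripts instead of genes, and the planned tests of gene lists in the RNA, of expression inside and outside domains, and of RNA changes in region-only domains were not run. Besides the area libraries, the authors gave files for whole cortex and subpallium. Their totals equal the sum of the 2 area libraries with the other replicate number (difference 0), so replicate numbers were exchanged between the sets of files. They served as an alternative only.

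Estimated counts were rounded to whole numbers, filtered with filterByExpr, normalised with TMM and fitted in edgeR 4.0.16 (R 4.3.3) with 4 area means. Quasi-likelihood F tests, two-sided, compared cortex (mean of PFC and V1) with subpallium (mean of LGE and MGE), LGE with MGE and PFC with V1, at a Benjamini-Hochberg adjusted p under 0.05. The SE given for a transcript is its absolute log2 difference divided by the square root of its F statistic. In 57730 transcripts with simulated changes in 200 of them, the cortex and subpallium test recovered 2% of 2-fold, 20% of 4-fold and 52% of 16-fold changes. Of its calls, 8.70% were unchanged transcripts. The data gave 2575 calls, far more than the simulation changed. More changes ease the adjusted threshold, so recovery in the data may be higher. Transcripts with at least 10 counts numbered from 43321 (PFC replicate 1) to 51962 (V1 replicate 1) per library, and the 10 most abundant took 31.9% to 53.9% of counts. Whether replicates are separate litters is not given in the sources used here. P-values then measure only the spread between these samples, which may be technical.

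Domains were laid on 10 kb bins, and a bin counted when at least 0.5 of it lay in a domain. A group with 2 lists was represented by the bins in both. Overlap of 47 pairs of sets was compared with 10000 circular shifts of a set along each chromosome, which keep domain lengths and spacing (permutation test, two-sided, smallest p 0.0002). The chromosome span ran from the first to the last base called in any list of that build. Shares of a chromosome are given as percent of this span, which can be shorter than the chromosome. In 200 simulated pairs of independent sets 6.5% had p under 0.05, and all of 50 pairs with part of 1 set copied to the other did. Sequence was called cortex-only when it lay in both cortex lists and neither subpallium list, and likewise for other pairs; for comparisons between tissues, NPC sequence had to lie in all 4 NPC lists. All software for domains was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures used matplotlib 3.10.9.

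Mouse genes came from a RefSeq gene table (21627 protein coding genes). It holds no strand, so a gene was placed by its body, with at least 0.5 in domain bins, instead of by its start site. Human and macaque genes were not analysed here. The 33 gene lists (identity, cell type, tissue and family lists) were each compared with all other genes by Fisher's exact test, adjusted over lists within a set, with exact binomial 95% intervals that cover counting only. Neighbouring genes share domains and are not independent, so circular shifts of the share difference were the check. Across the 7 mouse LaminB sets, 74 of 231 pairs of list and set passed Fisher's exact test, 47 above and 27 below other genes, and of these 22 above and 1 below also passed by circular shifts. Differences between tissues were tested by Fisher's exact test of list members against other genes in either tissue alone, adjusted over lists, without a shift check.

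The groups, tests, gene lists and alternatives were chosen before the data were examined, apart from the changes named here and 5 further alternatives chosen after seeing the data. Alternatives were RLE size factors, DESeq2 1.42.0, no count filter, a replicate block, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), a minimum effect, a 2-group model, the region-level files, 50 kb bins, any overlap, stricter domains (the upper part by score, or at least 100 kb), the union of lists, autosomes, and leaving out each library or list. Those added were other rules for placing a gene, the shift test, leaving out lists for gene groups, equal list lengths and autosomes for region-only domains. Items named follow a rule: for RNA, the largest changes among transcripts past the threshold with a mean log2 CPM above 3 and no overlap between groups, at most 2 per direction because they have no names; for domains, the 5 longest cortex-only and subpallium-only runs; for tissues, list members in the domains of a single tissue. The chromosomes named and the longest soluble-only run were chosen after their values were seen.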

Results

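The study asked how the genome is arranged relative to nuclear compartments in progenitor cells of the developing mammalian brain. GO-CaRT, the method of the study, brings a nuclease through an antibody to a nuclear structure in isolated nuclei, and the DNA released next to that structure is sequenced. An antibody to LaminB1, a protein of the nuclear lamina, reports chromatin at the nuclear periphery. An antibody to SON reports chromatin at nuclear speckles, interior bodies rich in splicing factors. H3K9me2 and H3K9me3, histone marks of repressed chromatin, were mapped with the same steps and antibodies to the marks, which the sample titles call GO-CaRT and the series design CUT&RUN. RNA sequencing of embryonic day (E) 13 mouse forebrain areas completed the set.

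Values came from 36 of the 62 samples, as 23 lists of domains called by the authors and 8 RNA libraries. The 17 mouse lists covered neural progenitor cells (NPCs, labelled NesGFP) from E13 cortex (2 LaminB lists and 1 H3K9me2 list) and E13 subpallium (2 LaminB lists), E13 liver (2) and E13 lung (2). They also covered cultured neural stem cells (NSCs) of the ventricular-subventricular zone (V-SVZ) of postnatal day 7 (1 LaminB list) and NIH/3T3 cells, a mouse embryonic fibroblast line. NIH/3T3 had LaminB lists from total (2) and soluble (2) material, 2 H3K9me2 lists and 1 H3K9me3 list. HEK293T, a human embryonic kidney line, had 2 LaminB and 2 SON lists, and E80 macaque had 1 LaminB list each for cortex and for the medial ganglionic eminence (MGE). RNA came from prefrontal cortex (PFC), primary visual cortex (V1), lateral ganglionic eminence (LGE) and MGE, with 2 libraries each. PFC and V1 stood for cortex, and LGE and MGE for subpallium.

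The domain lists gave no library totals, so their depth is unknown here; reads per domain, given for the cortex NPC H3K9me2 list alone, were not used here. The cortex NPC LaminB lists held 743 domains (979.8 Mb) in replicate 1 and 596 (1042 Mb) in replicate 2. Subpallium NPC lists held 604 (936 Mb) and 673 (1066 Mb) domains. Liver lists held 245 (825 Mb) and 223 (711 Mb), and lung lists 151 (938 Mb) and 111 (851 Mb). The cultured NSC list held 263 domains (975 Mb) and the cortex NPC H3K9me2 list 1022 (1049.7 Mb). In NIH/3T3, LaminB lists held 557 (925 Mb) and 537 (826 Mb) domains from total material and 753 (1040.1 Mb) and 522 (1199.6 Mb) from soluble material. The NIH/3T3 H3K9me2 lists held 421 (1035 Mb) and 395 (1427 Mb) domains, and the H3K9me3 list 379 (123 Mb). HEK293T lists held 751 (985 Mb) and 761 (987 Mb) LaminB domains and 564 (539.9 Mb) and 466 (512 Mb) SON domains. Macaque lists held 1398 domains (1161 Mb) in cortex and 1770 (993 Mb) in MGE. Total estimated counts of the RNA libraries in replicates 1 and 2 were 16177005 and 14186248 in PFC, 21241800 and 15703626 in V1, 23688343 and 20850718 in LGE, and 20796210 and 17523915 in MGE.

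In HEK293T cells, LaminB and SON domains almost never occupied the same place, and some chromosomes held almost only 1 kind. Shares are of the span between the first and last called base of a chromosome. SON domains covered 76.0% and 77.5% of chromosome 19 in replicates 1 and 2, and 73.9% and 80.0% of chromosome 22. LaminB domains covered at most 0.0137% of either of these chromosomes. Chromosome 13 showed the opposite picture, with 64.1% and 60.4% in LaminB domains and 0.64% and 0.02% in SON domains. Chromosome 17 followed 19 and 22 (SON 53.7% and 53.1%, LaminB 1.05% and 0.54%), and chromosome 4 followed 13 (LaminB 52.3% and 53.0%, SON 2.32% and 1.64%). Chromosome 1 held both kinds in like amounts (LaminB 32.7% and 34.7%, SON 28.9% and 27.8%). Chromosome 21 held much of both kinds, with 34.0% and 37.5% in LaminB domains and 59.0% and 61.7% in SON domains. The comparison tested whether the lamina and speckle maps separate 2 nuclear compartments in a line with both antibodies. Of the LaminB bins of 10 kb, 0.907% were also SON bins, 0.0888 times the share under circular shifts of the domains (832 bins; permutation p = 0.0002, the smallest 10000 shifts can give). The Jaccard index (shared over joined length) between replicates was 0.869 for LaminB and 0.776 for SON, so the separation was far larger than the difference between lists of the same antibody.

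In NIH/3T3 fibroblasts, LaminB domains of soluble material contained nearly all those of total material and extended beyond them. Of the total-material bins, 98.8% were soluble bins. For single lists this share was 97.6% to 99.7%. Bins in both soluble lists, which were the longer ones, and in neither total list made up 101.5 Mb with 415 genes. The longest soluble-only run, on chromosome 2 from 178020001 to 179630000, held Cdh4, a cell adhesion cadherin, Sycp2, a component of the meiotic chromosome axis, and Phactr3. LaminB domains of total material also lay mostly within H3K9me2 domains: 92.1% of their bins were H3K9me2 bins, 2.23 times the share under shifts (permutation p = 0.0002).

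H3K9me3 domains of the fibroblasts kept apart from the fibroblast LaminB domains, at 0.482 times the overlap under shifts for total and 0.494 times for soluble material (permutation p = 0.0002 for each). Their overlap with H3K9me2 did not differ from shifts (0.951 times; permutation p = 0.618), but with the union of the H3K9me2 lists it was above shifts (1.19 times; permutation p = 0.0040), as it was with H3K9me2 replicate 2 alone (1.19 times; permutation p = 0.0034). Zinc finger genes stood out in them: 96 of 367 Zfp genes, a family in which many members silence transposons, lay in H3K9me3 domains. That share was 26.2% (95% exact interval 21.7 to 31.0) against 1.79% of other genes (Fisher's exact test, adjusted p = 1.66e-74; by shifts, adjusted p = 0.0066). Protocadherins, adhesion molecules encoded in gene clusters, had 33 of 69 members (47.8%) in H3K9me3 domains. This passed Fisher's exact test (adjusted p = 2.82e-35) but not the shift test (adjusted p = 0.558), which treats a gene cluster as a unit. With LaminB domains of other mouse cells, fibroblast H3K9me3 overlapped more than under shifts. The values were 1.44 times for cortex NPCs, 1.45 for subpallium NPCs, 1.42 for cultured NSCs and 1.36 for liver (permutation p of at most 0.0078). With lung it did not differ from shifts (1.15 times, permutation p = 0.217). The H3K9me3 comparisons rest on 1 list.

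In E13 NPCs, LaminB domains were poor in genes and rich in long neuronal adhesion and synapse genes and in olfactory receptor genes. Cortex NPC domains held 3.02 protein coding genes per Mb against 11.3 outside, and 2624 of 21627 genes (12.1%) had at least 0.5 of their body in them. Among the 2426 genes over 100 kb the share was 22.7%, a nearer baseline for long genes that was not used in the tests. Of 50 long neuronal genes, 31 lay in cortex NPC domains (62.0%, 95% exact interval 47.2 to 75.3) against 12.02% of other genes. The difference passed Fisher's exact test (adjusted p = 1.64e-15) and the shift test (adjusted p = 0.0066). Of these, 29 lay in all 4 NPC lists, among them Cntnap2, Csmd3, Dlg2 and Robo2, genes of synapse organisation and axon guidance, and also Erbb4, the neuregulin receptor. Olfactory receptor genes had 502 of 1110 members in cortex NPC domains (45.2%, 42.3 to 48.2; shift adjusted p = 0.0066) and 546 in subpallium NPC domains (49.2%). Ionotropic glutamate and GABA receptor genes, the fast transmitter receptors of the brain, had 15 of 38 in cortex (39.5%, 24.0 to 56.6) and 16 in subpallium (42.1%), each with a shift adjusted p of 0.0132. Keratin-associated protein genes, products of hair, had 24 of 56 in cortex domains (42.9%; Fisher's exact test, adjusted p = 9e-08), which did not pass the shift test (adjusted p = 0.986).

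Histone, Hox, and lamina and speckle protein genes were absent from NPC domains. Of all 21627 genes, 16414 lay in none of the 4 NPC lists and 2330 in all 4. No histone gene (0 of 57) and no Hox gene (0 of 39) lay in any of the 4 NPC lists, and neither did any of the 20 genes for lamina and speckle proteins and their chromatin partners, such as Lmnb1, Son, Lbr and Ehmt2. Of 30 housekeeping genes 27 lay in none of the 4 lists, of 80 ribosomal protein genes 67, and of 20 mitosis genes 16. For ribosomal protein and mitosis genes these shares lay not far above that of all genes, and 2 ribosomal protein genes lay in all 4 lists. Zfp genes were fewer in cortex NPC domains than other genes (16 of 367, 4.36% against 12.3%; Fisher's exact test, adjusted p = 3.45e-06), a difference the shift test did not support (adjusted p = 0.998). Of the other groups of this paragraph, histone genes alone passed Fisher's exact test in cortex NPC domains (adjusted p = 0.00504), and none passed the shift test. Protocadherins (7 of 69), cytochrome P450 genes (7 of 99), potassium channels (12 of 80) and vomeronasal receptors (55 of 355) in cortex NPC domains did not pass Fisher's exact test against other genes (adjusted p of at least 0.177).

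LaminB domains of cortex NPCs lay mostly within H3K9me2 domains. Of the bins in both LaminB lists 94.9% were H3K9me2 bins (92.5% of replicate 1 and 84.7% of replicate 2 taken singly), and of the H3K9me2 bins 78.6% were LaminB bins, 2.02 times the share under shifts (permutation p = 0.0002; Jaccard index 0.754). The shared part, 825 Mb, held 2.69 genes per Mb. H3K9me2 outside both LaminB lists covered 85.9 Mb with 661 genes, and 202 of these were olfactory receptors (18.2% of the family against 2.24% of other genes; shift adjusted p = 0.0132). In the H3K9me2 list as a whole lay 855 of 1110 olfactory receptors (77.03%), 36 of 50 long neuronal genes (72.0%) and 19 of 38 ionotropic glutamate and GABA receptors (50.0%), each with a shift adjusted p of 0.0022. The H3K9me2 side of this comparison is 1 list, from PFC alone, whereas the LaminB lists joined PFC with V1.

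Cortex and subpallium NPCs shared most of their LaminB domains. Sequence in all 4 lists came to 803 Mb of the 1204 Mb in any list (66.7%), and the bins of both cortex lists and of both subpallium lists had a Jaccard index of 0.841. Sequence in both cortex lists and neither subpallium list came to 8.87 Mb, in 106 runs with a median of 50 kb. The reverse came to 7.16 Mb in 69 runs with a median of 60 kb. The longest cortex-only run covered 1250 kb of chromosome 12 (mm10, 88860001 to 90110000) inside Nrxn3, which encodes the presynaptic adhesion protein neurexin 3 and spans 88722701 to 90334935. Further long cortex-only runs lay on chromosome 11 over Sgcd, a sarcoglycan gene (46868001 to 47268000), on chromosome 1 over Rdh10, an enzyme of retinoic acid synthesis, and Stau2, an RNA transport factor (16130001 to 16470000), and on chromosome 1 over Tram2, Tmem14a, Gsta3, Khdc1a, Khdc1b, Khdc1c and Kcnq5 (21070001 to 21410000). Another, on chromosome 11 from 48388001 to 48718000, touched no protein coding gene. The longest subpallium-only run covered 940 kb of chromosome 4 (96650001 to 97590000) from Cyp2j5 to the edge of Nfia, a transcription factor of glial development. It was followed by runs over Mpdz, a scaffold protein (chromosome 4, 81410001 to 82190000), Antxr2 (chromosome 5, 97660001 to 98020000), Cop1, a ubiquitin ligase (chromosome 1, 159020001 to 159330000), and Anks1b, a synaptic scaffold (chromosome 10, 89871001 to 90161000).

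**Figure D1:**
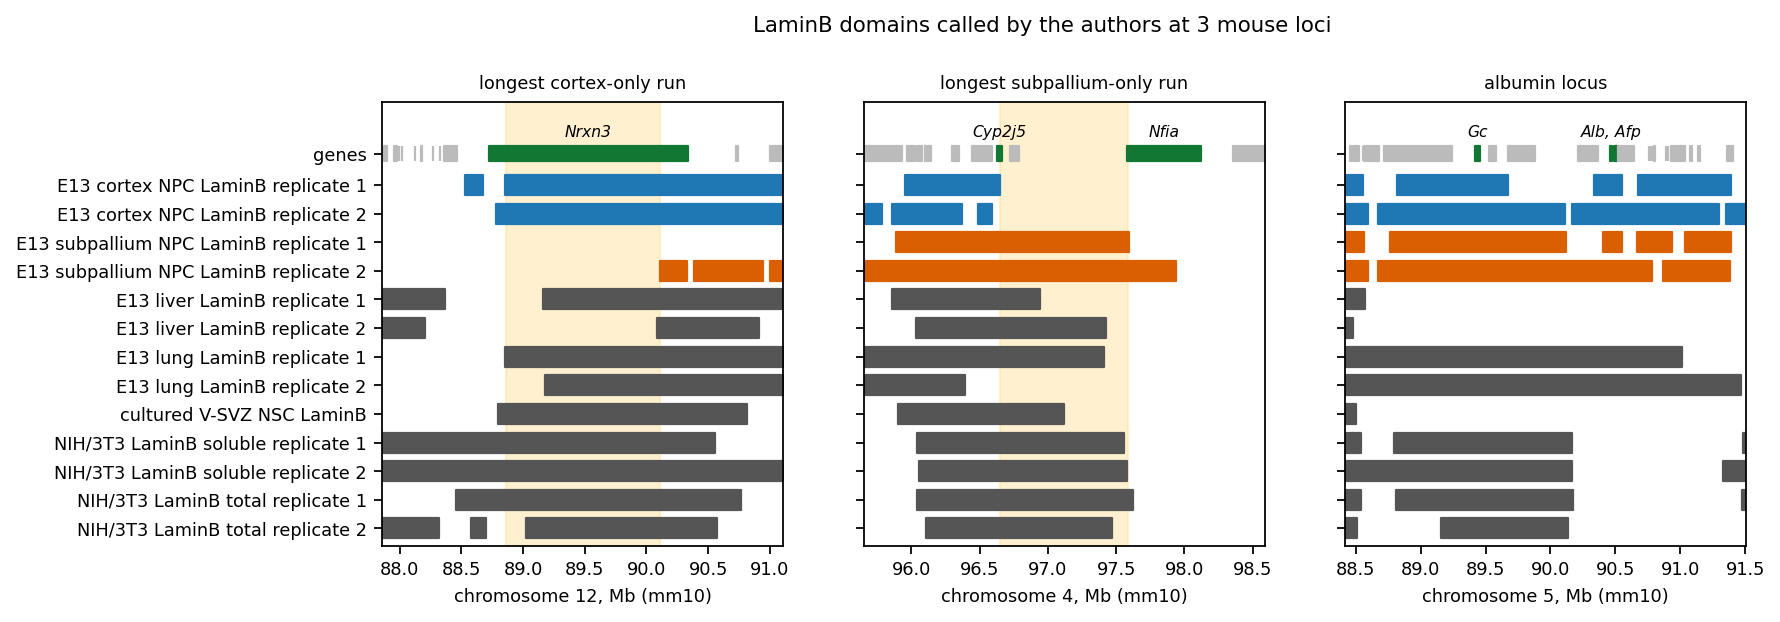
LaminB domains called by the authors in 13 mouse lists (bars, 1 line per list) along chromosomes 12, 4 and 5 in Mb of mm10, with protein coding genes on top and the longest cortex-only and subpallium-only runs shaded. The shaded runs are 1250 kb inside Nrxn3 and 940 kb between Cyp2j5 and Nfia. At the albumin locus, domains of the NPC and lung lists include Gc, Alb and Afp. Those of the liver and cultured NSC lists include none of these genes, and those of the NIH/3T3 lists include Gc but not Alb or Afp.

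Regional identity genes were looked up in the 4 NPC lists. Of 28 pallial identity genes none was cortex-only or subpallium-only: 3 lay in all 4 lists (Rprm, Dmrta1 and Neurod4), 13 lay in none, and Lhx9, Tbr1, Neurod1 and Bhlhe22 lay in all lists but cortex replicate 1. Of 32 subpallial identity genes none was region-only either: Foxp2 and Isl1 lay in all 4 lists, 21 lay in none, and Dlx5, Dlx6 and Sp8 lay in the replicate 2 list of both regions alone. None of the MGE, LGE, rostral or caudal patterning genes was region-only, and 13 of 21, 13 of 23, 8 of 17 and 10 of 20 of them lay in none of the lists. Of all 33 gene groups, long neuronal genes (Nrxn3), olfactory receptors (Olfr1366 in cortex, 8 genes in subpallium), Zfp genes (Zfp317 in cortex, Zfp62 in subpallium) and defensins (Defb37 in cortex) had region-only members. In total 34 genes were cortex-only and 42 subpallium-only by at least 0.5 of their body, of 21627, so a count of 0 in lists this short says little.

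The region-only sequence was smaller than the difference between lists of the same region. The cortex lists differed by 282 Mb and the subpallium lists by 229 Mb. These are differences within a pair of lists, whereas region-only sequence must agree across 4 lists, a stricter rule that lowers it. Grouped by replicate number instead of region, the 4 lists gave 25.8 Mb in replicate 1 alone and 88.3 Mb in replicate 2 alone. Leaving out a list of each region raised the region-only sequence to between 53.8 and 113 Mb for cortex and between 70.0 and 77.6 Mb for subpallium. With 3 ways of pairing 4 lists, an exchange of list labels cannot reach 0.05, and no other test of region was run, so the region-only runs are positions without a test.

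**Figure D2:**
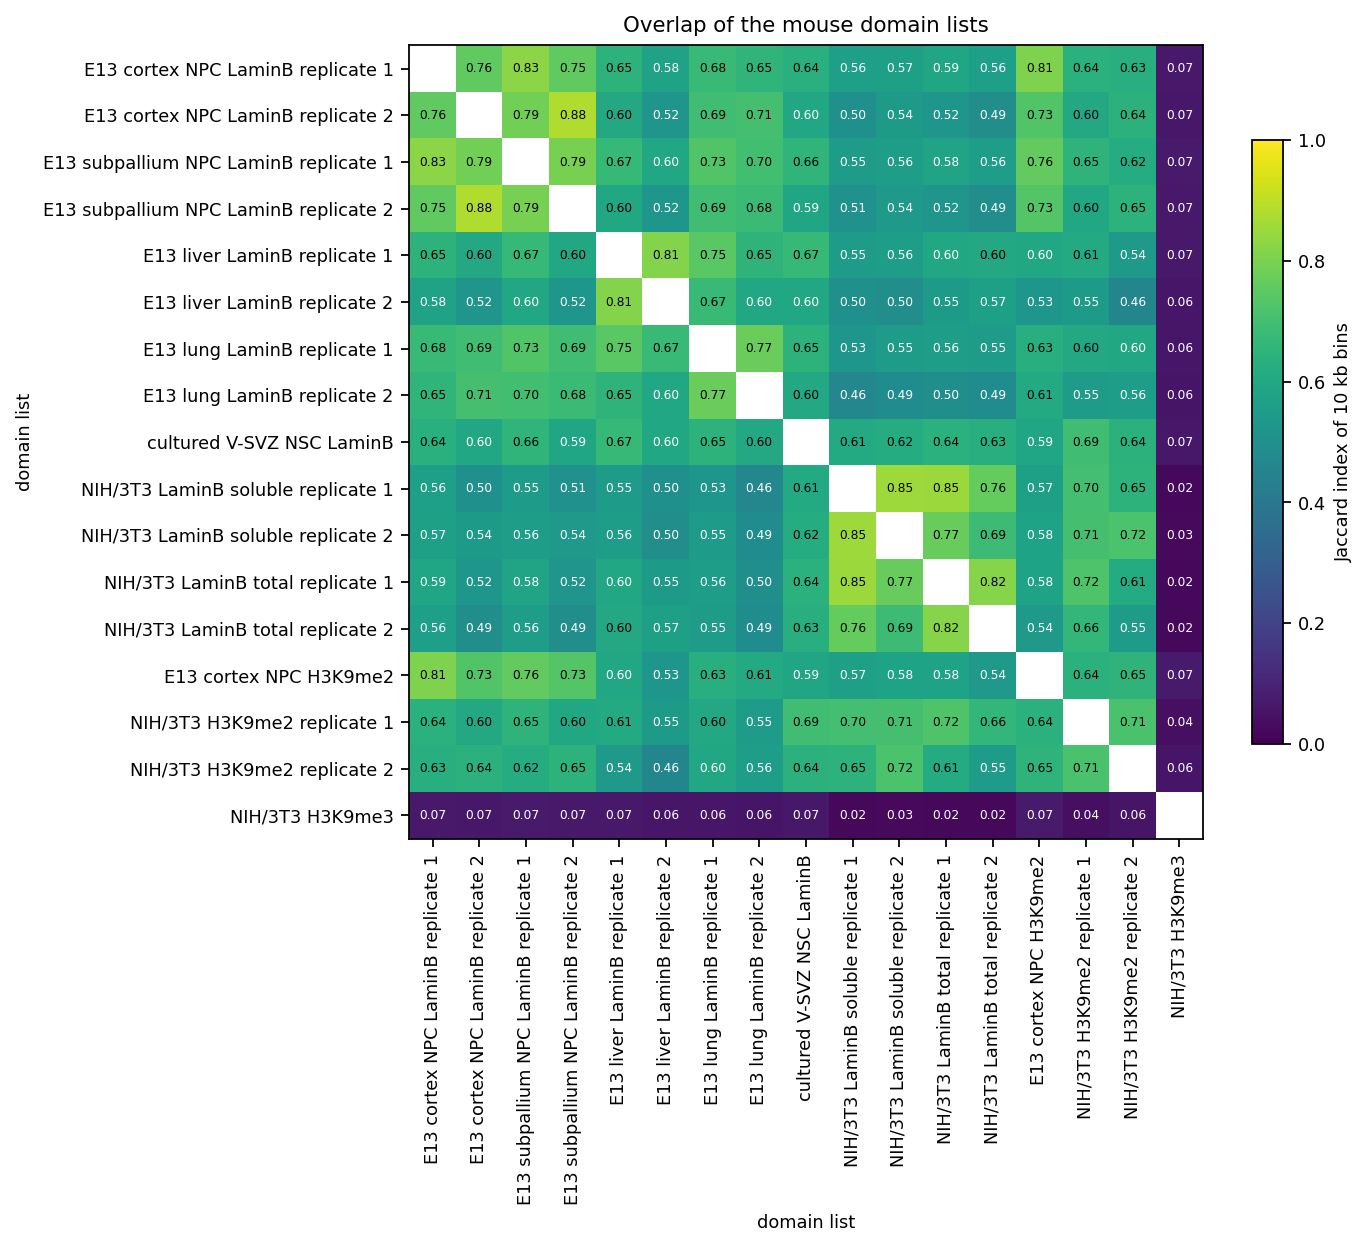
Jaccard index of 10 kb bins (colour scale from 0 to 1, no unit) for each pair of the 17 mouse domain lists, which label both axes. Cortex and subpallium NPC lists of replicate 2 reach 0.88 and those of replicate 1 reach 0.83, above the 0.76 and 0.79 between lists of the same region. The H3K9me3 list stays at 0.07 or below. It is by far the shortest list, which keeps its index low at any overlap.

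Across tissues, a common core of LaminB domains was rich in long neuronal genes and olfactory receptors, and the gene groups that differed between tissues past the test were families with clustered members. NPCs (all 4 lists), liver, lung, cultured NSCs and NIH/3T3 total material shared 396 Mb of the 1478 Mb in any of them (26.8%), with 974 genes. The core held 19 of 50 long neuronal genes (38.0% against 4.43% of other genes) and 366 of 1110 olfactory receptors (33.0%), each with a shift adjusted p of 0.0033. Long neuronal genes passed Fisher's exact test and the shift test in all 7 mouse LaminB sets, from 23 of 50 in liver (46.0%) to 43 of 50 in NIH/3T3 soluble material (86.0%). The Jaccard index between replicates was 0.814 in liver and 0.770 in lung, against 0.597 to 0.745 between single lists of liver and lung and 0.522 to 0.645 between those of cortex NPCs and liver. Single lists of NPCs and lung came closer, at 0.654 to 0.727, against 0.755 between the cortex NPC lists and 0.795 between the subpallium NPC lists. Pairs of LaminB sets overlapped 1.80 to 2.43 times as much as under shifts (permutation p = 0.0002 for each). NPC lists have another file layout than the lists of the other mouse tissues, so tissue and caller cannot be told apart in comparisons with NPCs.

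Liver domains took in gene clusters that NPC domains left out. The clustered protocadherins, adhesion molecules that give neurons their surface identity, had 26 members (Pcdha and Pcdhb genes) in both liver lists and no NPC list and 0 the other way (Fisher's exact test, adjusted p = 8.16e-09). Zfp genes went the same way, 37 against 1 (adjusted p = 3.45e-11), as did olfactory receptors, 116 against 6 (adjusted p = 6.16e-34). Vomeronasal receptors gave 26 against 10 and cytochrome P450 genes 11 against 1 (adjusted p = 0.00783 for each), among the latter Cyp3a11 and Cyp2c29, drug-metabolising enzymes of adult liver. The single P450 gene in NPC domains alone was Cyp7a1, the first enzyme of bile acid synthesis. Many members of these families lie side by side. The p-values of these and the other tests between tissues treat neighbours as independent, and no shift check was run on them. Some of these families also varied between the NPC lists by replicate number. Olfactory receptors had 90 members in both replicate 1 lists alone and 2 in both replicate 2 lists alone. Vomeronasal receptors had 45 and 0, Zfp genes 0 and 27, and protocadherins and P450 genes 0 and 0. Liver and NPC lists differ in layout as well, so the counts cannot be read as a tissue difference alone. NPC domains alone held the fetal liver genes Alb, Afp and Gc, which encode serum albumin, alpha-fetoprotein and the vitamin D binding protein (chromosome 5, Gc from 89417511 and Afp to 90508907). They also held Vim and Fabp7, marker genes of radial glia, and the macrophage genes Ptprc, Mrc1, P2ry12 and Pf4. These small groups did not differ from other genes in the test. With stricter domains the share of protocadherins in liver domains was 5.80% and that of P450 genes 1.01%, each below other genes instead of above.

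Lung against liver also differed by gene family, and which families did so depended on list length. Liver alone held 85 olfactory receptors, 26 protocadherins, 17 P450 genes and 10 defensins, each against 0 in lung alone (adjusted p = 7.96e-43, 3.4e-12, 5.98e-08 and 0.00011), with 10 Zfp genes against 1 and 20 vomeronasal receptors against 10 (adjusted p = 0.000678 and 0.00105). Lung alone held the fetal liver genes Cps1, Gc, Alb, Afp, Foxa1 and Ttr. It also held the brain genes Pax6, Neurog2, Tbr1, Neurod1 and Lhx9, and Map2, Stmn2 and Gap43, genes of neuronal cytoskeleton and axon growth. The tests for these groups gave adjusted p of at least 0.609. With the lists trimmed by score to 711 Mb, liver alone held 423 olfactory receptors but 0 protocadherins, 0 P450 genes and 0 defensins. Lung alone then no longer held Cps1, Ttr, Map2 or Stmn2. Lung lists had no domain on chromosome 19, where liver lists covered 13.4% and 10.0% of the called span. Genes of that chromosome could thus fall in liver alone only. NPCs against lung differed for olfactory receptors alone among the 33 groups, 21 against 3 (adjusted p = 0.00166), and those of the 21 from Olfr1491 to Olfr1505 lie on chromosome 19, where lung had no domain. Slc34a2 and Sftpb, genes of alveolar epithelium, lay in lung domains and in no NPC list.

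Cultured NSCs and fibroblasts both held vomeronasal receptor genes that lay in no E13 NPC list. In cultured NSCs 170 vomeronasal receptors were in the NSC list alone and 0 in NPCs alone (adjusted p = 7.37e-41), with 112 olfactory receptors against 11 (adjusted p = 9.52e-15). Vim and Fabp7 lay in all 4 NPC lists and not in the cultured NSC list. In NIH/3T3 total material 162 vomeronasal receptors lay in fibroblasts alone against 7 in NPCs alone (adjusted p = 3.36e-43), with 120 olfactory receptors against 17, 24 P450 genes against 1 and 22 Zfp genes against 6 (adjusted p = 1.02e-21, 4.05e-06 and 0.011). The fibroblast genes Col3a1, Prrx1 and Twist1 and the matrix genes Dcn and Lum lay in NPC domains and not in those of NIH/3T3. Coverage of the X chromosome also differed between these lists. Domains covered 64.99% of its called span in cultured NSCs and 36.0% to 62.0% in the NIH/3T3 LaminB lists. In the 4 NPC lists they covered 0.03% to 3.70%, and in the liver and lung lists 0% to 6.72%. Whether sequence of X, or of chromosome 19 in lung, was left out when domains were called is not given in the sources used here. Vomeronasal receptors of the cultured NSCs and of NIH/3T3 passed the shift test (302 of 355, 85.1%, and 296, 83.4%; adjusted p = 0.0022 for each), and cultured NSCs had 1 list. Cultured NSCs, of postnatal day 7, differ from E13 NPCs in both age and culture, which cannot be told apart.

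**Figure D3:**
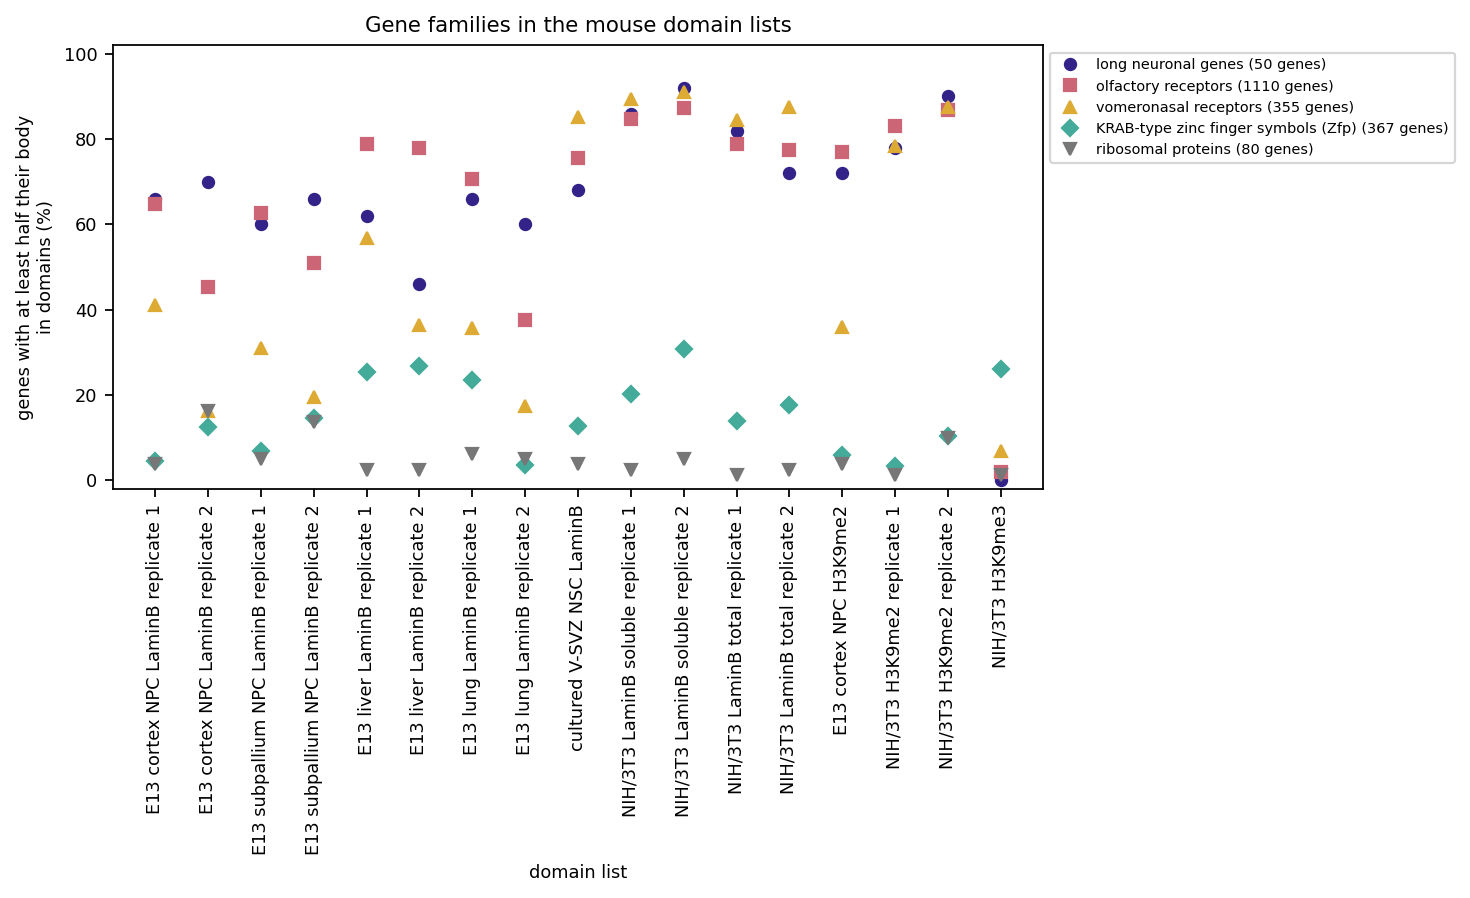
Share of the genes of 5 gene groups (symbols; percent on the vertical axis) with at least 0.5 of their body in the domains of each of the 17 mouse lists on the horizontal axis. Vomeronasal receptors reach 85.1% in cultured NSCs and stay at or below 41.1% in the 4 NPC lists, and Zfp genes reach 26.2% in the H3K9me3 list.

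In the E80 macaque forebrain, LaminB domains of cortex and MGE again overlapped strongly. Of the MGE bins 95.2% were cortex bins and of the cortex bins 80.8% were MGE bins, 1.76 times the overlap under shifts (permutation p = 0.0002; Jaccard index 0.776). Chromosomes 19 and 20 held little domain sequence (0.176 and 1.14 Mb in cortex, 0.168 and 1.94 Mb in MGE), and so did chromosomes 16 and 10 (1.24 and 4.36 Mb in cortex, 1.30 and 2.79 Mb in MGE). Chromosome 5 held 143 Mb in cortex and 123 Mb in MGE, or 79.5% and 68.4% of the span between its first and last called base. Each region had 1 list, so a regional difference cannot be set against replicate spread.

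RNA differed between cortex and subpallium of the E13 forebrain in 2575 transcripts. Of 57730 transcripts tested, 1370 were higher and 1205 lower in cortex (edgeR quasi-likelihood F test, adjusted p under 0.05), with a median absolute log2 difference of 1.49 among the called and 1765 over a log2 difference of 1. The transcripts carry identifiers that the files used here do not pair with gene names. Among those with the largest changes, ENSMUST00000029587 was higher in cortex by a log2 difference of 5.82 (SE 0.20, n = 4 libraries per region, adjusted p = 0.000284 from edgeR) and ENSMUST00000035020 by 5.39 (SE 0.22, adjusted p = 0.000425). ENSMUST00000159568 was lower, at -7.11 (SE 0.70, adjusted p = 0.00607), as was ENSMUST00000037119, at -6.93 (SE 0.27, adjusted p = 0.000375). The number called depended on the libraries: without LGE replicate 2 it was 906, without MGE replicate 2 it was 1029, without LGE replicate 1 it was 1049, without MGE replicate 1 it was 1138, without PFC replicate 1 it was 1350, without PFC replicate 2 it was 1366 and without V1 replicate 2 it was 1482. It was 7998 with DESeq2 and 1257 with limma on log2(TPM + 1), and it fell to 238 with the authors' pooled region-level files.

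Within subpallium, LGE and MGE differed in 163 transcripts, 130 higher and 33 lower in LGE, with a median absolute log2 difference of 2.30. ENSMUST00000210477 (log2 difference 7.23, SE 0.81, adjusted p = 0.0481 from edgeR) and ENSMUST00000041685 (6.81, SE 0.20, adjusted p = 0.00177) were higher in LGE. The former was hardly detected in MGE (mean log2 CPM -2.13 against 4.93 in LGE), so the size of its difference is uncertain. ENSMUST00000032768 (-2.52, SE 0.28, adjusted p = 0.0493) and ENSMUST00000151281 (-1.99, SE 0.18, adjusted p = 0.0313) were lower. Leaving out any of the 4 libraries (LGE or MGE, replicate 1 or 2) left 9 to 21 calls. DESeq2 called 1785 and limma on log2(TPM + 1) 29.

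Within cortex, PFC and V1 differed in 28 transcripts, 11 higher and 17 lower in PFC. ENSMUST00000111063 (log2 difference 3.18, SE 0.10, adjusted p = 0.00658 from edgeR) and ENSMUST00000221850 (2.46, SE 0.20, adjusted p = 0.0492) were higher in PFC. ENSMUST00000032768 (-4.43, SE 0.31, adjusted p = 0.0383) and ENSMUST00000091458 (-3.75, SE 0.24, adjusted p = 0.0350) were lower. Without any one of the 4 libraries (PFC or V1, replicate 1 or 2) edgeR called 0 transcripts, with 4247 to 6853 at an unadjusted p under 0.05, while DESeq2 on all libraries called 1932 and limma on log2(TPM + 1) 8. The mean Pearson correlation of log2(TPM + 1) across transcripts, which are not independent replicates, was 0.915 between libraries of 1 area, 0.912 between areas of 1 region and 0.894 between regions. The ranges overlapped, at 0.893 to 0.933, 0.882 to 0.923 and 0.865 to 0.918. V1 replicate 1 correlated at 0.918 with LGE replicate 1 and at 0.893 with V1 replicate 2.

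**Figure D4:**
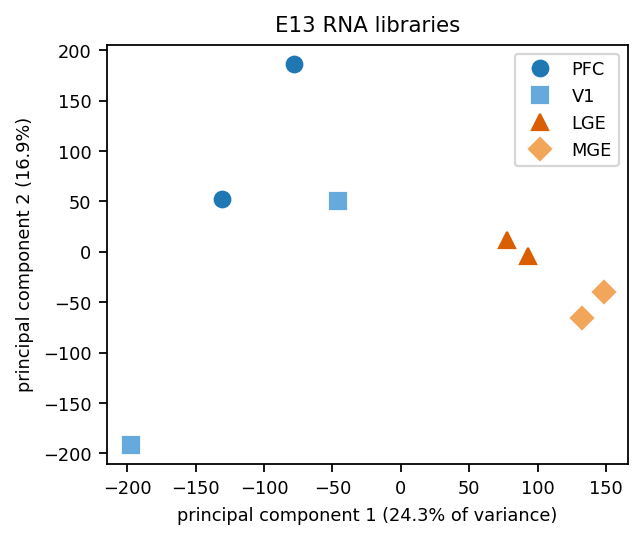
First and second principal components (arbitrary units; 24.3% and 16.9% of variance) of TMM-normalised log2 CPM (counts scaled to library size) of the 57730 tested transcripts in the 8 E13 RNA libraries, coloured by area. The 4 cortex libraries lie between -197 and -45.6 on the first component and the 4 subpallium libraries between 78.0 and 149, and the cortex libraries are the more spread along the second.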

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

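The test over splits of the RNA libraries was chosen before the result was seen, and the tests of list length, of exchanged labels and of list length in lung and liver were chosen only after it was seen.

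Regional difference in RNA. The 2-group comparison of 4 cortex and 4 subpallium libraries called 1866 transcripts. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many. The highest other split gave 3. The other splits mix regions, which widens their spread, and 35 splits cannot give a share below 1 in 35. Chance is thus an unlikely source of that number but is not excluded. The comparison also leaves open a difference in handling between cortex and subpallium samples, which the labels do not describe.

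Replicate number in the NPC LaminB lists. The 4 lists from E13 NPCs were parted by replicate number (114 Mb) more than by region (16.03 Mb), the pattern that a biologist looking for regional domains would most want explained. The replicate 2 lists hold more sequence, but with all lists trimmed by score to 936 Mb the replicate numbers were still parted by 128.9 Mb and the regions by 22.9 Mb, which argues against list length as the whole cause. Exchanged labels of cortex replicate 2 and subpallium replicate 1 cannot be told apart from correct ones: the exchange would make the split by replicate number the split by region, and the cortex H3K9me2 list, a single list, overlapped subpallium replicate 1 more than cortex replicate 2, by 0.0303 in Jaccard index. The identity genes in the replicate 2 lists alone, which would then be the subpallium lists, were Dlx5, Dlx6 and Sp8 of the subpallial list and Neurog2 of the pallial list. The prediction for an exchange was that pallial genes are gained and subpallial ones lost there. The direction went against it, but the genes were too few to decide, and Dlx5 and Dlx6 are neighbours. An exchange of cortex replicate 1 with subpallium replicate 2 would give the same split, with the replicate 2 lists as cortex. The genes of the subpallial list would then go with an exchange and Neurog2 against it. The H3K9me2 list overlapped cortex replicate 1 more than subpallium replicate 2 (Jaccard index 0.807 against 0.731). The genes thus do not speak against exchanged labels as such. Domain lengths also followed replicate number. In cortex and subpallium the longest domain was 13.0 and 15.5 Mb in replicate 1 and 38.4 and 37.8 Mb in replicate 2. The median was 576 and 696 kb in replicate 1 and 360 and 336 kb in replicate 2. A batch shared by equal replicate numbers, which was not tested, may also be at work. Regional biology stays open: the remaining pairing, cortex replicate 1 with subpallium replicate 2, parted the lists by 11.3 Mb, or 8.51 Mb at equal length.

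Fetal liver genes in lung. Alb, Afp, Gc, Cps1, Foxa1 and Ttr, genes of hepatocytes, lay in both lung lists and no liver list, but so did the fetal lung genes Slc34a2 and Sftpb. With the 4 lists trimmed by score to 711 Mb, Gc, Alb, Afp and Foxa1 remained in lung alone, at 2 places over 5 Mb apart, and none in liver alone. More sequence called in the lung lists may explain part of the pattern, and 2 places are too few to tell.

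Differences between tissues that passed the test of list members against other genes concerned these families, each counted in the domains of the tissue with more members. Liver over NPCs had 116 olfactory receptors, 26 vomeronasal receptors, 37 Zfp genes, 26 protocadherins and 11 cytochrome P450 genes. NPCs over lung had 21 olfactory receptors. Liver over lung had 85 olfactory receptors, 20 vomeronasal receptors, 10 Zfp genes, 26 protocadherins, 17 P450 genes and 10 defensins. With the lists trimmed to 711 Mb, liver alone held 423 olfactory receptors against 0 in lung alone, 23 vomeronasal receptors against 14, 30 Zfp genes against 2, and 0 protocadherins, P450 genes or defensins; these counts were not tested. Cultured NSCs over NPCs had 112 olfactory and 170 vomeronasal receptors. NIH/3T3 over NPCs had 120 olfactory and 162 vomeronasal receptors, 22 Zfp genes and 24 P450 genes. Many members of a family lie side by side, so these counts are not independent observations.

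The number of transcripts with at least 10 counts in LGE replicate 1, 51593, stood above the other 3 subpallium libraries (47311 to 47858). This library also had the largest total of all, 23688343 estimated counts. It was the only one past its limit of 12 such tests, and with that many tests chance alone may pass 1.

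Sequence outside the comparisons also carried domains. On the mouse Y chromosome they covered 2.37 Mb in liver replicate 1, 2.84 Mb in liver replicate 2, 2.91 Mb in lung replicate 2 and 32.0 Mb in cultured NSCs. On unplaced sequence they covered 12.3 Mb in macaque MGE, 4.59 Mb in macaque cortex, 1.85 and 1.54 Mb in NIH/3T3 soluble replicates 1 and 2, and 1.07 Mb in NIH/3T3 total replicate 2.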

How the results depend on the processing

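Alternatives for gene placement, shifts and left-out lists in gene groups, equal list lengths and autosomes for region-only domains were chosen after seeing the data. Of 317 overlap values under alternatives, 313 kept direction and side of the threshold. Lung LaminB and NIH/3T3 H3K9me3 passed it with the union of lists (1.26 times) and without replicate 2 (1.28; 1.14 without replicate 1), and H3K9me2 and H3K9me3 of NIH/3T3 reversed from 0.951 to 1.19 with the union and to 1.19 without replicate 1 (0.948 without replicate 2). RNA calls (cortex and subpallium, LGE and MGE, PFC and V1) moved most: 600, 31 and 5 with a minimum effect; 7998, 1785 and 1932 with DESeq2, which includes all 2575, 163 and 28 main calls; 1257, 29 and 8 with limma on log2(TPM + 1); 1031 and 33 for the first pair of comparisons on log2(TPM + 0.1). Replicate numbers did not pair the libraries (correlation of replicate differences between areas, across transcripts, from -0.041 to 0.088); with the replicate block LGE and MGE gave 39 and PFC and V1 gave 1, and RLE gave 14 for PFC and V1. The region-level files, with fewer libraries, gave 238, of which 227 were shared. Without each library the counts ranged from 906 to 2392, from 9 to 21, and 0 in every PFC and V1 fit; the lone library of an area is then assumed to vary like the others. The alternatives set out for RNA gene lists, expression in domains and RNA changes in region-only domains were not run. Shares of gene groups gave 433 values that kept their call, 72 weaker and 13 reversed; by shifts, 22 pairs remained above and 1 below. Reversed under stricter domains were protocadherins (5.80%), P450 genes (1.01%) and defensins (0%) in liver, defensins in NIH/3T3 soluble and total material (2.82% each) and keratin-associated genes in cultured NSCs (0%). With the union of lists, Zfp genes (24.0%) and defensins (50.7%) in lung and histone genes in NIH/3T3 soluble material (36.8%) reversed. Without replicate 2, Zfp genes (23.4%; 3.54% without replicate 1) and defensins (50.7%) in lung reversed; without replicate 1, vomeronasal receptors in subpallium NPCs (19.4%) and histone genes in NIH/3T3 soluble material (36.8%). Grouped by replicate number instead of region, the NPC LaminB lists gave 25.8 Mb in replicate 1 alone and 88.3 Mb in replicate 2 alone. Cortex-only and subpallium-only sequence was 14.9 and 4.02 Mb with stricter domains. With a left-out replicate, where fewer lists must be shared, it ranged from 53.8 to 113 Mb and from 70.0 to 77.6 Mb. The causes of the other changes were not tested. At these depths the RNA test recovered 20% of simulated 4-fold changes, but only 200 transcripts were changed there, so recovery in the data may be higher. Without depth for the lists a missing domain cannot be told from a low read number.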

Other observations

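The test of own marker genes was chosen only after the result was seen.

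Marker genes of cell types were looked up in the 4 E13 NPC lists, where 2330 of all 21627 genes lay in all 4 lists and 16414 in none; these counts were not tested against each other. Microglia and macrophage genes had 4 of 15 in all 4 NPC lists (Ptprc, Mrc1, P2ry12 and Pf4) and 11 in none. Endothelial genes had 3 of 15 in all lists (Emcn, Tek and Slco1c1) and 10 in none, and mural and meningeal genes 3 of 17 (Col3a1, Dcn and Lum) and 9 in none. Erythroid genes, which include the globin genes, had 0 of 15 in all lists and 10 in none. Choroid plexus and roof plate genes had Prlr alone of 11 in all lists, and Cajal-Retzius and hem genes had Ndnf and Rspo3 of 17. Of 23 postmitotic neuron genes, 14 lay in none of the lists. Fetal lung genes had Wnt2, Hhip and Fgf10 of 26 in all lists, and fibroblast genes Col3a1, Prrx1, Fap and Twist1 of 20. Radial glia and progenitor genes had Vim and Fabp7 of 19, and fetal liver genes had Gc, Alb and Afp of 32.

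Fibrinogen genes and forkhead factors of the liver varied with replicate number: Fga, Fgb, Fgg, Foxa1, Foxa2 and Itih2 lay in the replicate 2 lists of cortex and subpallium NPCs and in neither replicate 1 list. Replicate 2 of both regions shared 810 such genes and replicate 1 of both 219. Zfp genes gave 27 in the replicate 2 lists alone and 0 in the replicate 1 lists alone, whereas olfactory receptors gave 2 and 90 and vomeronasal receptors 0 and 45. These families were picked after their values were seen, and the counts were not tested. The pericyte genes Kcnj8 and Abcc9 lay in lung alone against liver, and no longer did with the lists trimmed to equal length.

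A hypothesis drawn from the fetal liver genes is that a tissue keeps its own marker genes out of its LaminB domains. Domains of NIH/3T3 also left out Alb and Afp, and those of cultured NSCs left out Gc, Alb and Afp. Absence at the albumin locus was thus not particular to liver. In 2 of 4 marker lists more members lay in the domains of the other tissue alone: fetal liver genes, which prompted the hypothesis, gave 0 in liver and 3 in NPCs, and fibroblast genes 0 in NIH/3T3 and 3 in NPCs. Of the other 3 lists, the fibroblast list alone went that way. RNA came from forebrain areas alone, so whether the listed genes were active in liver, lung or NIH/3T3 is not known here. Fetal lung genes gave 2 in lung (Slc34a2 and Sftpb) and 1 in NPCs (Hhip), and radial glia genes gave 2 in NPCs (Vim and Fabp7) and 0 in liver. With so few members per list the hypothesis may hold for some tissues and not for others, and the data cannot tell.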
